A study of Mus musculus with 23 samples.

How the data were processed

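Gene expression was measured by RNA sequencing in 23 libraries of macrophages and monocytes sorted from C57BL/6J mice with or without a poly(ethylene glycol) hydrogel under the skin. Per the series' design note, macrophages were Cx3cr1-positive and Ly6C-low and monocytes Cx3cr1-positive and Ly6C-high, which is read here as the sort. Per the labels' protocols, tissue was digested with Liberase TM, and libraries were made with SMART-Seq v4 and Nextera XT and sequenced as single reads of 75 bases on a HiSeq instrument. Per the submitters' processing notes, reads were converted with bcl2fastq, aligned to GRCm38 with STAR 2.4.1d and assigned to genes with featureCounts of Subread 1.5.1. The annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here. The deposited values are counts per gene and library, whole numbers in 47729 gene entries. Symbols, coordinates and exon lengths came from GENCODE M21, which gave a symbol to 47224 entries, and the other 505 held 0.11% of the counts. No pair of libraries had identical counts.

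Libraries were grouped by cell type and time as labelled, into 8 groups of 3 except the macrophage controls with 2. Library totals ran from 9303153 to 32994092 counts with a median of 24722229. Before TMM scaling, 3 counts correspond to 0.091 to 0.32 CPM. Of the 47729 entries, 20566 had 0 counts in every library. The comparisons, tests, gene lists, rule for naming genes and most alternatives were chosen before the data were examined.

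Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr by group, which left 16260, and scaled with TMM factors. A quasi-likelihood model with robust dispersion was fitted to all 23 libraries with 8 groups and tested by F tests in 17 contrasts. These were each cell type at each day against its controls, successive days within each cell type, the cell types against each other at each time, and the interactions of implant and cell type. A further test compared the 4 monocyte groups at once, and another the cell types over days 2, 14 and 28 with day as a factor. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 fold changes used a prior count of 0.125, and their standard error is the absolute log2 fold change over the square root of F. For a group with 0 counts, a bound was computed against 3 counts over the group, and with 1 to 3 counts a ratio with its counting interval. These treat reads as independent and leave out the wider spread between libraries. No covariate was used, since the replicate letters are not described.

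In each comparison of 2 groups, the 5 largest rises and the 5 largest falls were named among called genes with a mean of at least 10 CPM and no overlap between the groups' libraries. Predicted and unnamed genes, immunoglobulin and T cell receptor segments, mitochondrially encoded genes and sex-linked check genes were left out of these. Up to 4 members with the smallest adjusted p were named for each list described, and genes of the sort gate were followed. Zfp169 was named outside this rule. Some genes that the rule picks are not reported here. The 37 lists tested, each with 5 or more tested members, were written from general knowledge, and they cover macrophage and monocyte states, metabolism, stress and other cell types. They were tested with camera at a preset correlation of 0.01, and also with an estimated correlation and with fry.

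The alternatives were DESeq2 size factors (RLE), no low count filter, DESeq2 1.42.0, limma voom with quality weights, counts thinned to the lowest total, only the groups compared, all libraries in the overall tests, a replicate block, a prior count of 2 and leaving out each library in turn. A covariate for the transcript length trend, leaving out 3 libraries with a differing length trend or mitochondrial share, and lists matched on exon length and level were added after the data were seen. Matched lists drew each member, independently of the others, from the 150 nearest genes. The length trend and these lists used exon length, the summed annotated exons of a gene.

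Simulated counts with 2-fold and 4-fold changes tested the methods. Recovery was not split by level. The edgeR test recovered 6.0% and 56.0% of 200 genes changed at each size for macrophages at day 2 against controls, with 5.3% of calls false. It recovered 8.0% and 69.0% of 100 genes for monocytes at day 2 (6.1% false), 10.3% and 78.0% of 300 between the cell types at day 2 (3.3% false), and 0.7% and 32.7% of 300 for the day 2 interaction (3.8% false). Over the 4 monocyte times it recovered 1.0% and 68.0% of 100 (4.2% false), and over the implant days 67.0% and 97.0% of 100 (2.9% false). DESeq2 recovered 78.5%, 88.0%, 85.7% and 56.3% of the 4-fold changes in the first 4 settings, with 19.4%, 28.9%, 16.5% and 20.3% of calls false. For limma voom 6.1%, 5.6%, 5.7% and 3.8% were false. Camera passed 40 of 40 lists with 10 of 30 members changed and 0 of 40 unchanged. Genes were drawn independently, so correlation was not tested. Reads were not realigned, nor splicing or sequence variants analysed.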

Results

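Gene expression was measured by RNA sequencing in macrophages and monocytes sorted from mice that carried a poly(ethylene glycol) (PEG) hydrogel under the skin, and from mice without an implant. A PEG hydrogel is a synthetic, water-swollen polymer network, and the foreign body response is the inflammation and scarring that the body mounts around such a material. Both cell types carry the fractalkine receptor Cx3cr1. Macrophages were sorted as Ly6C-low and monocytes as Ly6C-high, Ly6C being a surface protein of circulating inflammatory monocytes. Libraries were made by SMART-Seq, a whole-transcript method for small RNA inputs. The 23 libraries form 8 groups, each cell type in controls and at days 2, 14 and 28 after implantation, with n = 3 per group except the macrophage controls (n = 2). The count filter left 16260 genes. Values in parentheses give the log2 fold change ± its standard error, then mean CPM (counts scaled by library total) in the first group against the second. A gene rose or fell where the edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05. Gene lists were written before the values were seen and were tested with camera from limma. Parentheses after a list give its members higher and lower, the counts adjusted over the list alone where these differ (alone), and camera's adjusted p. Camera's adjusted p with an estimated rather than preset correlation follows where it was 0.05 or more. The percentile of the list's median among 2000 lists matched on exon length and level follows unless it lay outside the central 95% of these in the list's direction. A range follows the number in the list's direction where leaving out 1 library moved it more than 1.5 times. The words at least and counting interval cover counting error only.

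Libraries of the same group had rank correlations of 0.92 to 0.97, against 0.82 to 0.95 for libraries of different groups. The first principal component held 33% of the variance and parted the 3 monocyte controls from the other 20 libraries. The second held 21.2% and parted the 2 macrophage controls.

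**Figure D1:**
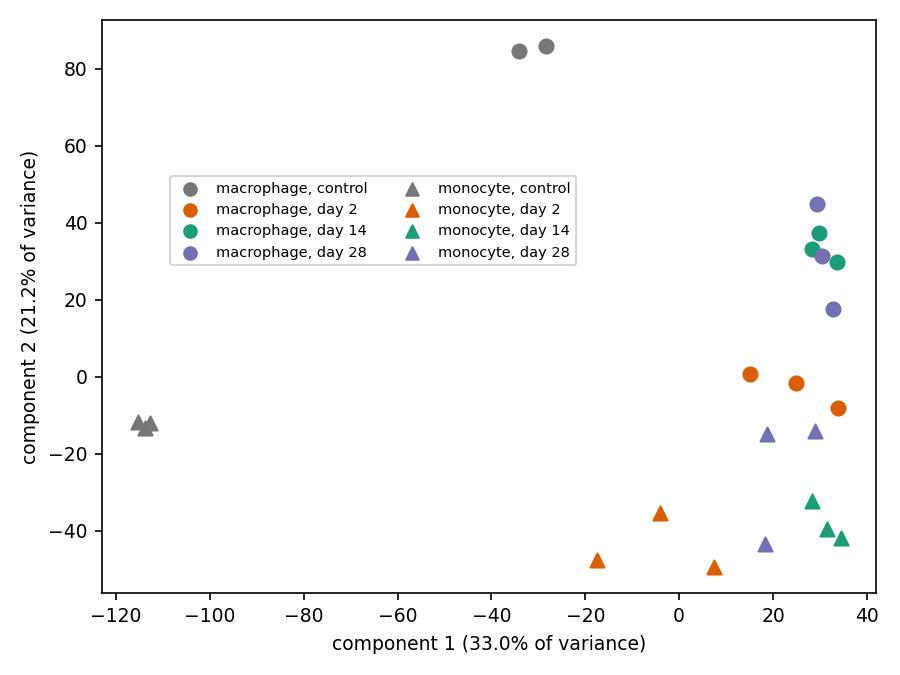
Principal components of the 1000 most variable genes over the 23 libraries. The first component held 33% of the variance and the second 21.2%.

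The first question was how subcutaneous macrophages without an implant differed from control monocytes (n = 2 against 3). Of 16260 genes, 1238 were higher in macrophages, 796 were lower and 14226 did not pass. Genes of tissue-resident macrophages were higher (29 of 32 higher, 0 lower, 30 and 0 alone, adjusted p = 3.8e-77). They included the endocytic adaptor Dab2 (11.58±0.64, 1129 against 0.357 CPM), the folate receptor Folr2 (12.02±0.74, 2312 against 0.548 CPM), the scavenger receptor Stab1 (9.60±0.61, 763 against 0.976 CPM) and the chemokine Pf4 (11.40±0.75, 1133 against 0.42 CPM). Complement genes were also higher (17 of 22 higher, 1 lower, adjusted p = 8.7e-37), among them C1qa (10.89±0.47, 2368 against 1.25 CPM) and the anaphylatoxin receptor C3ar1 (7.08±0.36, 661 against 4.86 CPM). The hyaluronan receptor Lyve1 (13.86±1.45, 556 against 0.0344 CPM) had the largest fitted rise, followed by Chp2 (at least 3168-fold higher, 75.6 CPM against 0 counts), C6 (at least 3125-fold higher, 74.5 CPM against 0 counts), Scamp5 (at least 2685-fold higher, 64 CPM against 0 counts) and C1qtnf1 (at least 2668-fold higher, 63.6 CPM against 0 counts). Lists of profibrotic mediators (14 of 29 higher, 2 lower, 15 and 3 alone, adjusted p = 5.2e-06), matrix proteases (11 of 23 higher, 2 lower, 12 and 2 alone, adjusted p = 1.5e-06) and alternative activation (13 of 30 higher, 5 lower, 14 and 5 alone, adjusted p = 1.5e-06) stood higher as well, with the growth factor Igf1 (7.49±0.93, 223 against 1.23 CPM), the mannose receptor Mrc1 (6.81±0.57, 1307 against 11.6 CPM) and the protease Ctsl (5.10±0.36, 1003 against 29.2 CPM).

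Control monocytes held more of the classical monocyte list (0 of 30 higher, 21 lower, 1 and 26 alone, adjusted p = 1.0e-24) and of the nonclassical list (0 of 26 higher, 15 lower, 1 and 16 alone, adjusted p = 1.5e-14). Among them were haptoglobin Hp (-6.58±0.55, 9.34 against 899 CPM) and the sialomucin Spn (-4.15±0.54, 3.19 against 56.3 CPM). Neutrophil genes were also higher in the control monocytes (0 of 14 higher, 10 lower, 0 and 11 alone, adjusted p = 3.5e-14), among them Ltf (-11.76±1.55, 0.11 against 379 CPM), Ngp (-11.49±1.38, 0.414 against 1108 CPM) and Camp (-11.17±1.39, 0.161 against 319 CPM). The elastase Elane (at least 699.5-fold lower, 0 counts against 43.1 CPM), outside this list, and the kinase Bmx (at least 282-fold lower, 0 counts against 17.4 CPM) were higher there too. The fibroblast list was higher in the macrophages (14 of 18 higher, range 9 to 12, 1 lower, 16 and 1 alone, adjusted p = 3.0e-10, estimated-correlation p = 0.084). Members included Sparc (7.23±0.97, 53 against 0.346 CPM) and Dcn (ratio 1484 with a counting interval of 508 to 7197, 35.4 CPM against 3 counts). The count was 1170 without macrophage control A and 1111 without macrophage control B.

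Macrophages at day 2 were compared with macrophage controls (n = 3 against 2). The question was how resident cells differ from cells next to a fresh implant. 1643 genes rose, 1154 fell and 13463 did not pass. The median change over all genes was -0.16. Inducible nitric oxide synthase, a source of antimicrobial nitric oxide, had the largest fitted rise (at least 1318-fold higher, 81.2 CPM against 0 counts; gene at chromosome 11, 78920787 to 78960254 on GRCm38). It was followed by the peptidase Klk9 (at least 549-fold higher, 33.8 CPM against 0 counts), the membrane protein Flrt3 (ratio 3428 with a counting interval of 615 to 135401, 70.4 CPM against 1 count), the protease inhibitor Slpi (10.49±0.95, 1255 against 0.833 CPM) and the calcium-binding alarmin S100a8 (10.43±1.17, 2307 against 1.58 CPM). Inflammatory cytokine genes rose (21 of 30 higher, 0 lower, 25 and 0 alone, adjusted p = 1.6e-22). They included oncostatin M Osm (4.03±0.37, 349 against 21.4 CPM), interleukin-1 beta Il1b (6.79±0.67, 3029 against 27.3 CPM) and the neutrophil attractant Cxcl2 (4.41±0.49, 2196 against 103 CPM).

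The day 2 macrophages also rose in hypoxia genes (20 of 22 higher, 0 lower, adjusted p = 1.0e-32) and glycolysis genes (18 of 24 higher, 1 lower, 20 and 1 alone, adjusted p = 1.1e-28). These held the glucose transporter Slc2a1 (5.85±0.47, 597 against 10.3 CPM), the lipid droplet protein Hilpda (6.75±0.58, 1492 against 13.9 CPM) and lactate dehydrogenase Ldha (3.15±0.29, 4788 against 540.2 CPM). Profibrotic mediators rose (13 of 29 higher, 2 lower, 14 and 3 alone, adjusted p = 1.1e-07). Members included the urokinase receptor Plaur (4.15±0.27, 1049 against 59.2 CPM), the protease inhibitor Timp1 (6.90±0.70, 209.7 against 1.75 CPM), osteopontin Spp1 (7.57±0.89, 49827 against 262 CPM) and the vessel growth factor Vegfa (7.51±0.94, 101 against 0.482 CPM). Osteopontin is a secreted matrix protein (gene at chromosome 5, 104435118 to 104441050). Arginase Arg1 (10.29±0.92, 9226 against 7.3 CPM), an enzyme of alternatively activated macrophages, rose too, although its list went both ways (10 of 30 higher, range 6 to 10, 7 lower, 13 and 7 alone, adjusted p = 0.16). Classical monocyte genes rose (16 of 30 higher, 0 lower, 17 and 1 alone, adjusted p = 1.2e-15). Among them were Hp (6.73±0.55, 997 against 9.34 CPM) and the lectin Clec4e (6.65±0.48, 1207 against 12.1 CPM). Immediate-early genes, which also answer to tissue digestion, rose as well (14 of 31 higher, 0 lower, 15 and 0 alone, adjusted p = 2.4e-09). These included Ier3 (3.91±0.36, 1568 against 104 CPM). Neutrophil genes moved with these lists (12 of 14 higher, range 7 to 12, 0 lower, 13 and 0 alone, adjusted p = 1.5e-13), among them S100a9 (10.43±1.18, 1949 against 1.32 CPM), lipocalin Lcn2 (9.79±1.23, 148 against 0.155 CPM) and Retnlg (7.01±1.09, 274 against 2.02 CPM).

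Resident macrophage genes fell at day 2 (2 of 32 higher, 21 lower, 3 and 22 alone, adjusted p = 3.5e-11), including the lectins Clec10a (-3.32±0.34, 103 against 1031 CPM), Mgl2 (-4.70±0.51, 36.4 against 944 CPM), Cd209g (-8.30±0.99, 1.66 against 443 CPM) and Cd209f (-7.47±1.24, 7.33 against 1224 CPM) and the sialic acid receptor Siglec1 (-3.45±0.44, 29.4 against 320.1 CPM). The aminopeptidase Enpep (-9.41±1.44, 0.193 against 92.2 CPM) had the largest fall, and complement C4b (-7.62±1.04, 4.34 against 821 CPM) and the adipokine-like C1qtnf1 (-7.50±1.24, 0.399 against 63.6 CPM) fell among the 5 largest. Cell cycle genes fell (1 of 50 higher, 19 lower, range 8 to 11, 1 and 28 alone, adjusted p = 6.3e-11). They included the replication helicase gene Mcm5 (-2.83±0.49, 6.59 against 46.4 CPM). Antigen presentation genes of MHC class II fell (2 of 16 higher, 8 lower, 2 and 9 alone, adjusted p = 1.4e-04, estimated-correlation p = 0.16). Members included their regulator Ciita (-4.50±0.58, 3.35 against 73.3 CPM) and the invariant chain Cd74 (-2.49±0.42, 2211 against 12427 CPM). Interferon response genes fell (0 of 50 higher, 15 lower, range 2 to 12, 1 and 18 alone, adjusted p = 1.4e-05, estimated-correlation p = 0.42). Among them was Oas2 (-3.91±0.59, 21.1 against 317 CPM). The fibroblast list was lower (0 of 18 higher, 7 lower, range 2 to 6, adjusted p = 2.0e-04, estimated-correlation p = 0.27). A member was Col1a2 (-4.16±0.92, 2.28 against 42.7 CPM). Members of the Cd209 family share sequence, and the handling of reads that map to several genes is not given in the sources used here, so their values are uncertain. With a covariate for the transcript length trend, added after the data were seen, the count was 1336. It was 826 without macrophage control A, 1681 without control B, 1621 without day 2 A and 1703 without day 2 C.

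Genes of oxidative phosphorylation (41 of 66 higher, range 1 to 40, 0 lower, 52 and 0 alone, adjusted p = 3.7e-16, estimated-correlation p = 0.19) and ribosomal proteins (22 of 64 higher, range 0 to 22, 0 lower, 35 and 1 alone, adjusted p = 8.2e-09, estimated-correlation p = 0.36) were higher in day 2 macrophages. Their exon lengths are short, and genes of like exon length and level rose at the same time. The medians were 1.37 for oxidative phosphorylation against 0.89 for matched lists, and 1.04 for ribosomal proteins against 0.47. The subunit gene Ndufa9 (1.30±0.25, 170.4 against 69.1 CPM) rose. Mitochondrially encoded genes rose as well (9 of 11 higher, range 2 to 9, 0 lower, 10 and 0 alone, adjusted p = 4.2e-07, estimated-correlation p = 0.17, percentile 93.4).

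At day 14 macrophages against controls (n = 3 against 2) had 896 genes that rose, 439 that fell and 14925 that did not pass. The largest fitted rises were Nos2 (at least 1000.3-fold higher, 61.6 CPM against 0 counts), Flrt3 (ratio 4755 with a counting interval of 854 to 187829, 97.7 CPM against 1 count), the sodium-proton exchanger Slc9b2 (ratio 1038 with a counting interval of 186 to 41018, 21.3 CPM against 1 count), the ectonucleotidase Nt5e (9.36±1.24, 94.4 against 0.123 CPM) and the cystine transporter Slc7a11 (9.29±0.65, 177 against 0.263 CPM). Hypoxia (17 of 22 higher, 0 lower, 20 and 0 alone, adjusted p = 2.3e-32), glycolysis (19 of 24 higher, 0 lower, 19 and 1 alone, adjusted p = 5.8e-30) and inflammatory cytokine lists (17 of 30 higher, 0 lower, 18 and 0 alone, adjusted p = 9.2e-19) were higher, with Slc2a1 (5.43±0.46, 447 against 10.3 CPM) and Il1b (5.45±0.63, 1196 against 27.3 CPM). Profibrotic mediators rose (13 of 29 higher, 1 lower, 15 and 2 alone, adjusted p = 3.2e-12), with Spp1 (7.69±0.90, 54121 against 262 CPM) and Vegfa (8.46±0.98, 195 against 0.482 CPM), and so did Arg1 (8.47±0.86, 2608 against 7.3 CPM). Genes linked to foreign body giant cells, which form by macrophage fusion, rose (10 of 30 higher, range 6 to 9, 0 lower, 13 and 2 alone, adjusted p = 4.2e-06): the tetraspanin Cd9 (6.23±0.61, 2839 against 37.8 CPM) and the adhesion receptor Cd44 (3.16±0.36, 634 against 71.1 CPM). Lysosomal genes rose (14 of 49 higher, range 4 to 13, 0 lower, 20 and 0 alone, adjusted p = 4.2e-10, percentile 40.4). They included the collagen-degrading cathepsin Ctsk (6.47±1.11, 639 against 7.17 CPM). Lipid handling genes rose (10 of 25 higher, 1 lower, 12 and 1 alone, adjusted p = 1.1e-08). Members included the oxidized lipid receptor Olr1 (4.64±0.43, 34.1 against 1.36 CPM). Iron and heme genes rose (9 of 21 higher, range 3 to 8, 1 lower, 11 and 2 alone, adjusted p = 8.1e-06). Among them was the oxidant defence enzyme Txnrd1 (3.10±0.41, 208 against 24.2 CPM).

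Resident macrophage genes remained lower at day 14 (1 of 32 higher, 16 lower, range 9 to 14, 1 and 22 alone, adjusted p = 4.6e-11). These included the apoptotic cell receptor Timd4 (-6.65±1.44, 0.874 against 87.5 CPM) (gene at chromosome 11, 46810800 to 46844332), Siglec1 (-3.63±0.44, 25.8 against 320.1 CPM), Cd209g (-6.42±0.90, 5.18 against 443 CPM), Cd209b (-5.85±1.49, 2.78 against 160.4 CPM) and Cd209f (-5.62±1.14, 24.9 against 1224 CPM). The membrane remodelling enzyme Dnm1 (-4.94±1.33, 0.816 against 25.1 CPM) was also among the 5 largest falls. The microglial marker Tmem119 (3.57±0.52, 223 against 18.8 CPM), a member of the same list, rose instead. Neutrophil list members moved with the inflammatory genes (3 of 14 higher, range 1 to 4, 0 lower, 4 and 0 alone, adjusted p = 0.0063, estimated-correlation p = 0.21). Members included S100a8 (6.04±0.98, 109.8 against 1.58 CPM) and S100a9 (4.76±0.92, 38.4 against 1.32 CPM). The count was 417 without macrophage control A and 727 without control B.

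At day 28 macrophages against controls (n = 3 against 2) had 1069 genes that rose, 648 that fell and 14543 that did not pass. Beside Nos2 (at least 581-fold higher, 35.8 CPM against 0 counts), Flrt3 (ratio 4429 with a counting interval of 795 to 174918, 91 CPM against 1 count), Slc9b2 (ratio 2047 with a counting interval of 367 to 80868, 42.1 CPM against 1 count) and Nt5e (10.20±1.27, 169 against 0.123 CPM), E-cadherin Cdh1 (at least 392-fold higher, 24.2 CPM against 0 counts), an adhesion protein, was among the largest fitted rises. Giant cell genes (11 of 30 higher, range 7 to 12, 0 lower, 14 and 1 alone, adjusted p = 1.0e-08) and matrix proteases (10 of 23 higher, 1 lower, 11 and 1 alone, adjusted p = 4.6e-08) rose, with Ctsk (7.89±1.19, 1711 against 7.17 CPM). Hypoxia (16 of 22 higher, 0 lower, 20 and 0 alone, adjusted p = 6.9e-28), glycolysis (17 of 24 higher, 0 lower, 19 and 0 alone, adjusted p = 6.9e-28) and profibrotic lists (15 of 29 higher, 1 lower, 16 and 4 alone, adjusted p = 1.5e-11) were still higher, with Slc2a1 (5.45±0.46, 454 against 10.3 CPM), Spp1 (7.91±0.90, 62829.7 against 262 CPM) and Timp1 (5.72±0.66, 92.2 against 1.75 CPM). Mitochondrially encoded genes rose (8 of 11 higher, range 0 to 8, 0 lower, 9 and 0 alone, adjusted p = 6.6e-08, estimated-correlation p = 0.14). Lysosome genes (19 of 49 higher, range 8 to 19, 0 lower, 30 and 2 alone, adjusted p = 1.4e-09, percentile 93.3) and lipid handling genes (11 of 25 higher, 1 lower, 15 and 2 alone, adjusted p = 1.6e-08) rose. Resident macrophage genes fell (1 of 32 higher, 22 lower, adjusted p = 4.5e-18). These included Clec10a (-3.65±0.35, 82.3 against 1031 CPM) and Siglec1 (-3.56±0.44, 27.1 against 320.1 CPM). Enpep (-6.48±1.20, 1.02 against 92.2 CPM), Timd4 (-6.39±1.42, 1.05 against 87.5 CPM), Cd209g (-7.73±0.95, 2.08 against 443 CPM), Cd209f (-7.55±1.24, 6.54 against 1224 CPM) and Cd209b (-6.17±1.51, 2.22 against 160.4 CPM) had the largest falls. The count was 809 without macrophage control A and 689 without control B.

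**Figure D2:**
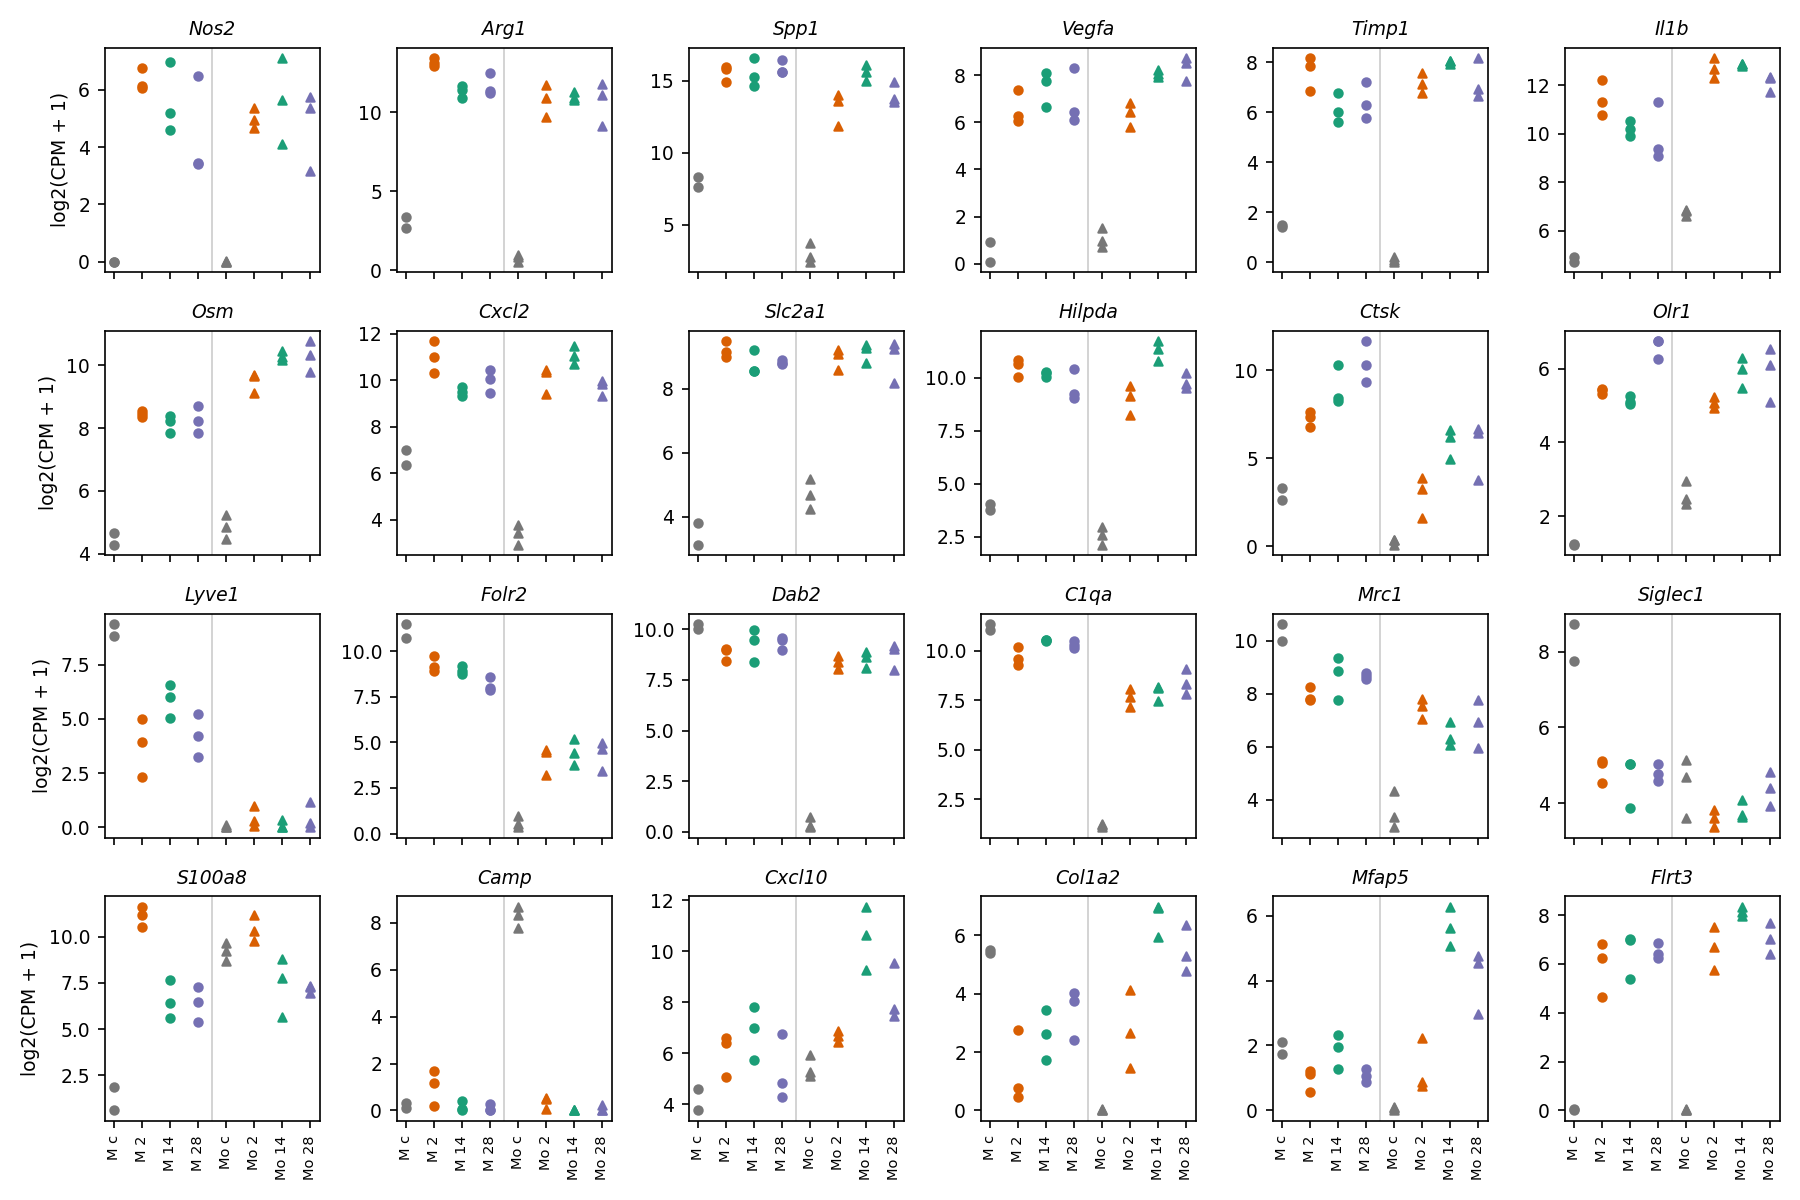
Log2 of CPM plus 1 for 24 genes named in the text. Each point is a library, with macrophages (M) as circles, monocytes (Mo) as triangles and controls marked c.

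Monocytes at day 2 were compared with monocyte controls (n = 3 against 3). The question was how Ly6C-high cells at the implant differed from those of mice without one. 2522 genes rose, 1867 fell and 11871 did not pass. The largest fitted rises were the aspartic peptidase Asprv1 (at least 2408-fold higher, 57.4 CPM against 0 counts), the platelet chemokine Ppbp (at least 2219-fold higher, 52.9 CPM against 0 counts) (gene at chromosome 5, 90768518 to 90770063), Flrt3 (ratio 14204 with a counting interval of 2549 to 561045, 113 CPM against 1 count), podoplanin Pdpn (at least 1093-fold higher, 26.1 CPM against 0 counts) and the membrane transporter Slc4a11 (at least 879.8-fold higher, 21 CPM against 0 counts). Inflammatory cytokine genes rose (24 of 30 higher, 0 lower, 24 and 1 alone, adjusted p = 4.1e-30). Members included Cxcl2 (6.84±0.46, 1109 against 9.68 CPM), Osm (4.66±0.32, 727 against 28.7 CPM) and Ccl7 (10.76±0.80, 344 against 0.196 CPM). Complement genes rose (13 of 22 higher, 1 lower, 15 and 1 alone, adjusted p = 5.2e-17). Among them was C3ar1 (7.03±0.35, 638 against 4.86 CPM). Resident macrophage genes rose in the monocytes (15 of 32 higher, 2 lower, 16 and 2 alone, adjusted p = 1.5e-11). These included Dab2 (9.83±0.60, 336 against 0.357 CPM) and Pf4 (9.32±0.69, 268 against 0.42 CPM). The sample labels give subcutaneous tissue for controls and implants alike. Control monocytes carried granule transcripts, with Ngp at 1108 CPM, and lay apart on the first component. A different source or maturity of these cells would enter every comparison with them and each interaction, and was not tested.

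Day 2 monocytes rose in profibrotic mediators (21 of 29 higher, 3 lower, adjusted p = 9.5e-12) and matrix proteases (15 of 23 higher, 0 lower, adjusted p = 5.4e-11). They included Timp1 (10.62±0.70, 145 against 0.0853 CPM), Spp1 (10.47±0.83, 10858 against 7.67 CPM) and Ctsl (5.86±0.36, 1694 against 29.2 CPM). Arg1 (11.42±0.80, 2024 against 0.734 CPM) and the scavenger receptor Msr1 (2.54±0.23, 1186 against 203 CPM) rose within the alternative activation list (17 of 30 higher, range 11 to 15, 2 lower, 18 and 2 alone, adjusted p = 1.2e-07). Hypoxia (15 of 22 higher, 0 lower, adjusted p = 1.1e-17) and glycolysis genes (17 of 24 higher, 0 lower, 18 and 0 alone, adjusted p = 9.9e-16) were higher, with Hilpda (6.75±0.48, 545 against 5.06 CPM) and Ldha (3.21±0.24, 3392 against 366 CPM). Fibroblast genes moved with the profibrotic list (12 of 18 higher, 0 lower, 14 and 0 alone, adjusted p = 1.5e-05, estimated-correlation p = 0.23). A member of both lists was Sparc (5.66±0.90, 17.9 against 0.346 CPM).

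Granule protein genes were among the 5 largest falls in day 2 monocytes: Camp (-10.07±1.08, 0.293 against 319 CPM), Ltf (-7.58±1.02, 1.95 against 379 CPM) and Ngp (-7.20±0.93, 7.46 against 1108 CPM). The immunoglobulin joining chain Jchain (ratio 1175 with a counting interval of 402 to 5697, 3 counts against 68.2 CPM) and the egress receptor S1pr5 (-7.56±1.44, 0.219 against 41.7 CPM) completed the 5. Members of the neutrophil list went both ways (5 of 14 higher, 3 lower, 5 and 4 alone, adjusted p = 0.66), and Retnlg (7.82±0.94, 208 against 0.911 CPM) rose. Nonclassical monocyte genes fell (6 of 26 higher, 13 lower, 7 and 13 alone, adjusted p = 0.017, estimated-correlation p = 0.11), with Pou2f2 (-2.85±0.34, 8.58 against 62 CPM), while Cd9 (5.06±0.48, 673 against 20.1 CPM) rose. Cell cycle genes were lower as a list (4 of 50 higher, 10 lower, range 4 to 7, adjusted p = 4.3e-04, estimated-correlation p = 0.16), with Racgap1 (-4.22±0.74, 4.23 against 79.7 CPM), although Gins2 (2.04±0.42, 7.42 against 1.8 CPM) and Cenpa (1.63±0.39, 39.1 against 12.6 CPM) rose. Oxidative phosphorylation genes were higher (52 of 66 higher, range 27 to 51, 0 lower, 53 and 0 alone, adjusted p = 8.5e-12, estimated-correlation p = 0.25), with a median of 1.29 against 0.92 for matched lists, and so were mitochondrially encoded genes (10 of 11 higher, 0 lower, adjusted p = 4.0e-06, estimated-correlation p = 0.20, percentile 96.8). The count was 2573 with the length covariate, 2811 without monocyte control A and 2724 without control C.

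At day 14 monocytes against controls (n = 3 against 3) had 3226 genes that rose, 2906 that fell and 10128 that did not pass, the largest number of calls of the 6 comparisons with controls. The collagen genes Col1a1 (at least 1787-fold higher, 42.6 CPM against 0 counts) and Col1a2 (ratio 12927 with a counting interval of 2320.2 to 510606, 103 CPM against 1 count) joined Flrt3 (ratio 35663 with a counting interval of 6401 to 1408627, 284 CPM against 1 count), Pdpn (at least 4687-fold higher, 112 CPM against 0 counts) and Ppbp (at least 1992-fold higher, 47.5 CPM against 0 counts) among the largest fitted rises. Inflammatory (26 of 30 higher, 0 lower, 28 and 0 alone, adjusted p = 2.5e-30), profibrotic (21 of 29 higher, 1 lower, adjusted p = 6.1e-16) and matrix protease genes (16 of 23 higher, 1 lower, 19 and 1 alone, adjusted p = 3.4e-12) rose, with Osm (5.46±0.33, 1265 against 28.7 CPM), Timp1 (11.46±0.72, 259 against 0.0853 CPM), Spp1 (12.67±0.89, 50135 against 7.67 CPM) and Ctsl (5.77±0.36, 1589 against 29.2 CPM). The fibroblast list moved with them (15 of 18 higher, 0 lower, 16 and 0 alone, adjusted p = 7.0e-10, estimated-correlation p = 0.095). Members included Mfap5 (10.21±0.94, 52.6 against 0.0376 CPM) and Sparc (9.68±1.04, 289 against 0.346 CPM). Interferon response genes rose (21 of 50 higher, range 12 to 24, 1 lower, 23 and 2 alone, adjusted p = 6.2e-04, estimated-correlation p = 0.55). A member was Cxcl10 (5.43±0.82, 1880.5 against 43.8 CPM).

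Complement (15 of 22 higher, 1 lower, 17 and 2 alone, adjusted p = 1.8e-15) and resident macrophage genes (15 of 32 higher, 2 lower, 16 and 2 alone, adjusted p = 4.5e-09) were higher in day 14 monocytes, with C3ar1 (7.65±0.36, 978 against 4.86 CPM) and Dab2 (10.02±0.61, 383 against 0.357 CPM). Arg1 (11.43±0.80, 2030.1 against 0.734 CPM) rose, as did the iron and heme list (12 of 21 higher, 0 lower, adjusted p = 3.5e-06). A member was heme oxygenase Hmox1 (3.31±0.35, 1093 against 110.2 CPM). Hypoxia genes rose (18 of 22 higher, 0 lower, 19 and 0 alone, adjusted p = 2.2e-19). Neutrophil genes fell (2 of 14 higher, 8 lower, adjusted p = 0.0021, estimated-correlation p = 0.16). These included Camp (at least 5714-fold lower, 0 counts against 319 CPM), Ngp (ratio 59622 with a counting interval of 10701 to 2354931, 1 count against 1108 CPM) and Ltf (-8.07±1.05, 1.43 against 379 CPM). Myeloperoxidase Mpo (-8.22±1.15, 0.108 against 34.5 CPM), Jchain (at least 1224-fold lower, 0 counts against 68.2 CPM) and S1pr5 (ratio 1122 with a counting interval of 311 to 9265, 2 counts against 41.7 CPM) made up the 5 largest falls together with Camp and Ngp. Oxidative phosphorylation (53 of 66 higher, 2 lower, adjusted p = 3.2e-12, estimated-correlation p = 0.25) and ribosomal protein lists (42 of 64 higher, range 18 to 45, 1 lower, 46 and 1 alone, adjusted p = 2.4e-06, estimated-correlation p = 0.51) were higher, and so were mitochondrially encoded genes (9 of 11 higher, 0 lower, 10 and 0 alone, adjusted p = 1.9e-04, estimated-correlation p = 0.29, percentile 45.5). The ribosomal median was 1.07 against 0.51 for matched lists. The count was 3108 with the length covariate.

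At day 28 monocytes against controls (n = 3 against 3) had 1905 genes that rose, 1060 that fell and 13295 that did not pass. Pdpn (at least 2443-fold higher, 58.3 CPM against 0 counts), Flrt3 (ratio 17606 with a counting interval of 3160.0 to 695412, 140.0 CPM against 1 count), Ppbp (at least 1458-fold higher, 34.8 CPM against 0 counts) and Slc4a11 (at least 1384-fold higher, 33 CPM against 0 counts) were among the largest fitted rises. Inflammatory (25 of 30 higher, 0 lower, 27 and 0 alone, adjusted p = 1.7e-35), complement (17 of 22 higher, 0 lower, 18 and 0 alone, adjusted p = 3.4e-24), profibrotic (22 of 29 higher, 0 lower, adjusted p = 6.3e-23) and resident macrophage lists (17 of 32 higher, 0 lower, 21 and 0 alone, adjusted p = 7.2e-17) were higher. They held Osm (5.51±0.33, 1307 against 28.7 CPM), C3ar1 (7.33±0.35, 784 against 4.86 CPM), Spp1 (11.25±0.85, 18713 against 7.67 CPM) and Dab2 (10.25±0.61, 448 against 0.357 CPM). Arg1 (11.46±0.80, 2082 against 0.734 CPM) rose, and so did the cholesterol exporter Abca1 (5.86±0.53, 306 against 5.27 CPM) within the lipid handling list (14 of 25 higher, 3 lower, 16 and 3 alone, adjusted p = 2.3e-07). The fibroblast list was higher beside the profibrotic genes (14 of 18 higher, 0 lower, 16 and 1 alone, adjusted p = 6.5e-12). A member was Mfap5 (8.69±0.90, 18.3 against 0.0376 CPM). Camp (ratio 6228 with a counting interval of 2131 to 30201, 3 counts against 319 CPM), Ngp (-12.33±1.19, 0.225 against 1108 CPM), Ltf (-10.38±1.18, 0.287 against 379 CPM), S1pr5 (-8.06±1.48, 0.149 against 41.7 CPM) and Mpo (-7.92±1.12, 0.138 against 34.5 CPM) had the largest falls. Nonclassical genes fell (7 of 26 higher, 12 lower, 7 and 13 alone, adjusted p = 0.0046), as did the neutrophil list (1 of 14 higher, 8 lower, range 5 to 7, 3 and 9 alone, adjusted p = 3.9e-04, estimated-correlation p = 0.10). Immediate-early genes were higher in each of the 6 comparisons with controls. In macrophages 14 of 31 rose at day 14 (9 to 13 with 1 library left out) and 12 at day 28 (2 fell), and in monocytes 16, 17 and 15 rose at days 2, 14 and 28 (4, 6 and 1 fell), with an estimated-correlation p of 0.058 at day 14. Whether digestion was the cause was not tested. The count was 1962 without monocyte control A and 1932 without control C.

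**Figure D3:**
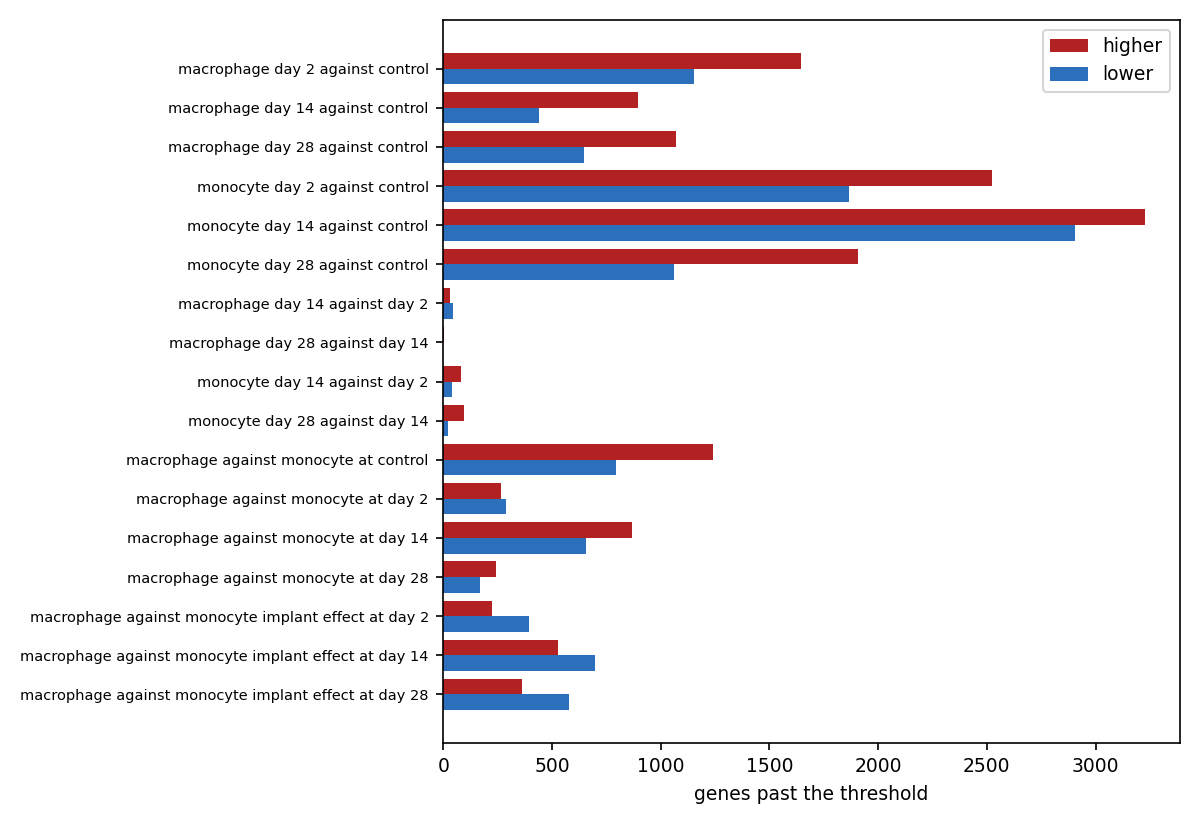
Genes that rose and fell in each comparison by the edgeR quasi-likelihood test at an adjusted p under 0.05. Bars start at 0.

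Changes between implant days were asked for next, each with n = 3 against 3. In macrophages from day 2 to day 14, 32 genes rose, 45 fell and 16183 did not pass. The receptor kinase Axl (3.82±0.58, 149 against 10.8 CPM), which clears apoptotic cells, rose with Slc9b2 (6.71±1.14, 21.3 against 0.174 CPM), C4b (4.46±0.89, 91.9 against 4.34 CPM), the integrin chain Itgax (3.74±0.72, 114 against 8.7 CPM) and Olfml3 (3.48±0.49, 44.7 against 4.03 CPM). MHC class II genes rose (6 of 16 higher, range 1 to 8, 0 lower, 8 and 0 alone, adjusted p = 7.1e-13). A member was Cd74 (2.30±0.39, 10925 against 2211 CPM). The largest falls were Klk9 (-9.09±1.64, 0.0598 against 33.8 CPM), the glucose transporter Slc2a3 (-7.28±1.28, 0.207 against 31.9 CPM), Lcn2 (-7.04±0.86, 1.13 against 148 CPM), Klk8 (-6.44±1.27, 0.578 against 50.2 CPM) and serum amyloid Saa3 (-6.39±1.00, 35.5 against 2969.6 CPM). Neutrophil genes fell (0 of 14 higher, 8 lower, range 3 to 7, 0 and 14 alone, adjusted p = 6.4e-34). Among them were S100a9 (-5.67±0.78, 38.4 against 1949 CPM) and Retnlg (-6.24±0.88, 3.62 against 274 CPM). Il6 (-4.38±0.81, 1.19 against 24.7 CPM) and the monocyte attractant Ccl2 (-2.27±0.47, 242 against 1163 CPM) fell within the inflammatory list (0 of 30 higher, 2 lower, range 0 to 2, 3 and 11 alone, adjusted p = 2.9e-07, estimated-correlation p = 0.12). By DESeq2 the count was 334 and by limma voom 721, with 682 without a count filter. It was 34 without day 2 A, 42 without day 2 B, 32 without day 14 A and 29 without day 14 B.

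In macrophages from day 14 to day 28, 1 gene passed by the edgeR quasi-likelihood test, 1420 had an unadjusted p under 0.05, DESeq2 gave 40 and limma voom 79. It was the zinc finger gene Zfp169 (4.06±0.62, 5.89 against 0.35 CPM), named after its values were seen since its level lies under the rule's floor of 10 CPM. The count was 0 without day 14 A, B or C or without day 28 A or B, and 24 without day 28 C. No member of the resident macrophage list passed, although the list was lower as a whole (0 of 32 higher, 0 lower, range 0 to 1, 0 and 8 alone, adjusted p = 1.3e-06, estimated-correlation p = 0.072).

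In monocytes from day 2 to day 14, 79 genes rose, 39 fell and 16142 did not pass. The interferon-induced chemokine Cxcl10 (4.22±0.77, 1880.5 against 101 CPM) rose with Mfap5 (4.96±0.71, 52.6 against 1.73 CPM), Sparc (4.02±0.80, 289 against 17.9 CPM), Rilpl1 (3.93±0.90, 19.2 against 1.24 CPM) and the collagenase Mmp13 (3.84±0.90, 35.8 against 2.53 CPM). Interferon genes rose as a list (3 of 50 higher, range 0 to 10, 0 lower, 25 and 0 alone, adjusted p = 6.9e-25, estimated-correlation p = 0.12), as did profibrotic (2 of 29 higher, range 0 to 1, 0 lower, 14 and 0 alone, adjusted p = 1.9e-12), lipid handling (2 of 25 higher, range 0 to 3, 0 lower, 12 and 1 alone, adjusted p = 3.8e-09) and iron and heme genes (3 of 21 higher, range 0 to 5, 0 lower, 7 and 1 alone, adjusted p = 6.9e-07). Among them were Rsad2 (3.14±0.66, 1252 against 142 CPM), Pdgfb (3.27±0.73, 7.12 against 0.746 CPM), Nr1h3 (2.29±0.36, 77.8 against 15.9 CPM) and Hmox1 (1.54±0.33, 1093 against 376 CPM). The fibroblast list rose beside the profibrotic genes (3 of 18 higher, range 0 to 3, 0 lower, 11 and 0 alone, adjusted p = 3.0e-18). A member was Col1a2 (3.73±0.85, 103 against 7.84 CPM). The largest falls were Chil1 (-5.55±0.93, 0.908 against 44.1 CPM), Asprv1 (-5.48±1.16, 1.27 against 57.4 CPM), the gelatinase Mmp9 (-5.21±0.94, 2.68 against 97 CPM), Retnlg (-5.02±0.83, 6.43 against 208 CPM) and Lcn2 (-3.62±0.72, 13.6 against 167 CPM), and the neutrophil list fell (0 of 14 higher, 5 lower, range 0 to 4, 0 and 12 alone, adjusted p = 8.8e-21). DESeq2 gave 586 genes, limma voom 538 and the unfiltered test 741. The count was 16 without day 2 B, 0 without day 2 C, 52 without day 14 A and 14 without day 14 C.

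In monocytes from day 14 to day 28, 96 genes rose, 21 fell and 16143 did not pass. Apolipoprotein E Apoe (3.61±0.79, 10874 against 894 CPM), a lipid carrier, rose with Tmem70 (3.67±0.64, 27 against 2.14 CPM), Tsen34 (3.35±0.70, 34.1 against 3.35 CPM), Arhgap9 (3.16±0.71, 179.7 against 20.1 CPM) and Rbfa (3.07±0.71, 50.3 against 5.99 CPM). The integrin chain Itgb1 (1.83±0.43, 309.9 against 87.1 CPM) rose. The largest falls were Cd24a (-1.85±0.42, 20.4 against 73.6 CPM), S100a11 (-1.84±0.42, 609 against 2176 CPM), Ifitm6 (-1.69±0.35, 77.1 against 248 CPM), Dubr (-1.40±0.27, 26.3 against 69.3 CPM) and Ifi207 (-1.30±0.29, 207 against 511 CPM). No interferon list member passed, while the list was lower as a whole (0 of 50 higher, 0 lower, range 0 to 3, 0 and 14 alone, adjusted p = 5.7e-11, estimated-correlation p = 0.62). DESeq2 gave 1513 genes, limma voom 334 and the replicate block 2, and each of the 11 genes named here lost its call in at least 1 alternative other than leaving out a library. The count was 0 without day 14 A or day 28 B, 13 without day 14 B, 4 without day 14 C, 252 without day 28 A and 65 without day 28 C.

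Over all 4 times, 4878 of 13530 genes tested in the 12 monocyte libraries changed by the edgeR quasi-likelihood test. Osteopontin Spp1 had mean levels of 7.67, 10858, 50135 and 18713 CPM in controls and at days 2, 14 and 28, and Cxcl10 43.8, 101, 1880.5 and 375 CPM. Mfap5, a microfibril gene of fibroblasts, had 0.0376, 1.73, 52.6 and 18.3 CPM. The count was 3236 without control A and 3123 without control C. It was 1612 with the length covariate.

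Macrophages and monocytes from the same implant day were compared next (n = 3 against 3 at each day). At day 2, 266 genes were higher in macrophages, 290 were lower and 15704 did not pass. The chemokine Ccl8 (8.31±0.82, 1015 against 3.21 CPM), the scavenger protein Cd5l (8.27±1.43, 118 against 0.383 CPM), Fxyd2 (6.08±0.70, 30.4 against 0.461 CPM), the stress cytokine Gdf15 (5.84±1.33, 22.5 against 0.368 CPM) and the leukotriene synthase Ltc4s (5.63±0.63, 263 against 5.35 CPM) were highest relative to monocytes. Resident macrophage genes were higher (14 of 32 higher, range 7 to 14, 0 lower, 23 and 0 alone, adjusted p = 7.6e-25). A member was Folr2 (5.20±0.55, 635 against 17.3 CPM). Profibrotic genes (9 of 29 higher, range 2 to 7, 2 lower, 13 and 3 alone, adjusted p = 3.6e-06) and iron and heme genes (4 of 21 higher, 1 lower, 6 and 1 alone, adjusted p = 9.1e-06) were higher too, with Igf1 (4.48±0.80, 220.4 against 9.93 CPM) and Hmox1 (1.99±0.33, 1496 against 376 CPM). Classical monocyte genes were lower (0 of 30 higher, 15 lower, range 9 to 14, 0 and 20 alone, adjusted p = 9.1e-19). Among them was Cd177 (-4.71±0.67, 10.5 against 274 CPM). Fcnb (-5.88±1.01, 0.453 against 20.7 CPM), Spint1 (-4.98±1.20, 0.875 against 29.3 CPM) and Gpld1 (-4.31±0.78, 1.22 against 23.5 CPM) were among the lowest, together with Ly6c2 (-4.56±0.71, 67.2 against 1578 CPM), which encodes the sorted Ly6C protein. The count was 314, 269 and 316 without macrophage day 2 A, B or C, and 331 and 272 without monocyte day 2 B or C. DESeq2 gave 1176 and limma voom 1647.

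At day 14, 869 genes were higher in macrophages, 654 were lower and 14737 did not pass. Lyve1 (9.58±1.32, 62.8 against 0.0923 CPM), Scamp5 (7.23±0.82, 23.4 against 0.153 CPM), Ccl8 (6.96±0.77, 1599 against 12.8 CPM), the Axl ligand Gas6 (6.29±0.93, 174 against 2.21 CPM) and Cxcl14 (5.92±1.16, 47.4 against 0.777 CPM) were highest relative to monocytes, and resident macrophage genes were higher (20 of 32 higher, 1 lower, 23 and 1 alone, adjusted p = 7.6e-23). These included Mgl2 (4.28±0.48, 172 against 8.86 CPM). Inflammatory (0 of 30 higher, 13 lower, range 7 to 12, 0 and 15 alone, adjusted p = 2.1e-10, estimated-correlation p = 0.11) and interferon genes (0 of 50 higher, 18 lower, range 4 to 21, 0 and 36 alone, adjusted p = 6.3e-19, estimated-correlation p = 0.21) were lower in macrophages, with Il1b (-2.64±0.46, 1196 against 7446 CPM) and Cxcl10 (-3.81±0.76, 135 against 1880.5 CPM). Classical monocyte genes were lower (0 of 30 higher, 21 lower, 0 and 24 alone, adjusted p = 2.3e-22), with Cd177 (-6.08±0.72, 1.95 against 132 CPM), and so were Ifitm1 (-4.86±0.69, 46.7 against 1361 CPM) and Ly6c2 (-5.66±0.75, 47 against 2378 CPM). The fibroblast list was lower in macrophages (0 of 18 higher, 10 lower, range 5 to 6, 0 and 14 alone, adjusted p = 1.4e-11, estimated-correlation p = 0.11). A member was Mfap5 (-4.25±0.68, 2.76 against 52.6 CPM). The count was 918 and 639 without macrophage day 14 A or B, and 863 and 635 without monocyte day 14 A or C. DESeq2 gave 2896 and limma voom 2869.

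At day 28, 242 genes were higher in macrophages, 167 were lower and 15851 did not pass. The signalling protein Rasgrp3 (7.46±1.32, 27.8 against 0.151 CPM), the resistin-like Retnla (6.59±1.05, 290.0 against 2.99 CPM), Mamdc2 (5.64±1.28, 77.6 against 1.54 CPM), Lyve1 (5.40±1.03, 20.8 against 0.479 CPM) and the proton pump subunit Atp6v0d2 (4.77±1.06, 483 against 17.7 CPM), which macrophage fusion uses, were highest relative to monocytes. Giant cell genes were higher (9 of 30 higher, range 3 to 11, 0 lower, 14 and 0 alone, adjusted p = 1.4e-06, estimated-correlation p = 0.070). Among them were Cd36 (3.06±0.51, 2786 against 333 CPM) and Ctsk (4.69±0.84, 1711 against 66.1 CPM). Resident macrophage genes were higher (10 of 32 higher, range 5 to 12, 0 lower, 19 and 0 alone, adjusted p = 1.4e-14). A member was Folr2 (3.78±0.52, 290.2 against 21.2 CPM). Cd177 (-6.28±0.73, 1.87 against 145 CPM), Ly6c2 (-5.59±0.75, 27.6 against 1333 CPM), Ly6c1 (-4.18±0.51, 5 against 90.8 CPM) and Plac8 (-4.01±0.57, 53.5 against 862 CPM) were among the lowest, with classical monocyte genes as a list (0 of 30 higher, 12 lower, range 6 to 15, 1 and 19 alone, adjusted p = 8.0e-19). The count was 69, 128 and 1323 without macrophage day 28 A, B or C, 213 and 111 without monocyte day 28 A or C, and 1 with the 6 libraries alone. Each of the 12 genes named here lost its call in at least 1 alternative other than leaving out a library. DESeq2 gave 1199 and limma voom 1167.

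Over the 3 implant days together (n = 9 against 9, day as a factor), 1025 genes were higher in macrophages and 1078 lower of 14149 tested. Lyve1 (6.31±0.84, 33.3 against 0.334 CPM), Ccl8 (6.30±0.83, 929.5 against 12.7 CPM), Retnla (5.64±0.65, 293 against 5.65 CPM), Fxyd2 (4.61±0.46, 23.9 against 1.05 CPM) and Folr2 (4.49±0.33, 476 against 20.4 CPM) were highest relative to monocytes. Cd177 (-5.67±0.46, 4.77 against 184 CPM), Ly6c2 (-5.25±0.45, 47.2 against 1763 CPM), Plac8 (-3.90±0.36, 116 against 1679 CPM), Ly6c1 (-3.84±0.33, 8.19 against 118 CPM) and the peptidase inhibitor Pi16 (-3.05±0.33, 6.1 against 49.3 CPM) were lowest. Ly6c1 and Ly6c2 share sequence and belong to the sort, so their difference is part of the gate. No single library moved this count by more than 1.5 times, and leaving out the 3 libraries with a differing length trend or mitochondrial share together gave 1391.

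The last question was whether the implant effect differed between the cell types, by the interaction in the edgeR fit (n = 3, 2, 3 and 3). Values here are differences between log2 changes ± standard error. Lower monocyte control levels, as for Dab2 and Timp1, enter them. At day 2, 222 genes changed more upward in macrophages, 393 more downward and 15645 did not pass. Resident macrophage genes were relatively lower in macrophages (0 of 32 higher, 23 lower, 0 and 29 alone, adjusted p = 8.8e-61). Dab2 (-11.15±0.72) went from 1129 to 454 CPM in macrophages and from 0.357 to 336 CPM in monocytes, and Stab1 (-8.30±0.68) and Mrc1 (-6.34±0.68) differed likewise. Pf4 (-7.28±0.78) rose in both, from 1133 to 4641 CPM in macrophages and from 0.42 to 268 CPM in monocytes. Complement genes differed in the same direction (1 of 22 higher, 14 lower, 1 and 15 alone, adjusted p = 1.7e-42). C1qa (-8.82±0.50) went from 2368 to 847 CPM in macrophages and from 1.25 to 203 CPM in monocytes. MHC class II genes were relatively lower in macrophages (0 of 16 higher, 8 lower, range 4 to 10, 0 and 10 alone, adjusted p = 1.6e-10). These included H2-Eb1 (-2.94±0.62) and Lgmn (-2.93±0.37). Nonclassical monocyte (8 of 26 higher, range 5 to 7, 0 lower, 13 and 0 alone, adjusted p = 5.1e-10) and neutrophil genes (8 of 14 higher, 0 lower, 9 and 0 alone, adjusted p = 2.8e-17) were relatively higher, with Spn (4.65±0.65), S100a8 (9.12±1.21) and S100a9 (9.19±1.21). The count was 380 without macrophage control A and 401 without control B.

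At day 14, 529 genes changed more upward in macrophages, 698 more downward and 15033 did not pass. Inflammatory (0 of 30 higher, 13 lower, 1 and 18 alone, adjusted p = 8.1e-15), profibrotic (2 of 29 higher, 9 lower, 3 and 12 alone, adjusted p = 1.5e-05) and matrix protease genes (2 of 23 higher, 8 lower, 2 and 9 alone, adjusted p = 3.0e-05) were relatively lower in macrophages, with Cxcl2 (-4.99±0.55), Ccl2 (-5.49±0.70), Timp1 (-6.07±0.80) and Ctsl (-3.87±0.45). Resident macrophage (0 of 32 higher, 19 lower, 0 and 23 alone, adjusted p = 3.5e-37) and complement genes (1 of 22 higher, 14 lower, adjusted p = 5.8e-30) were relatively lower too, with Dab2 (-10.75±0.71), Stab1 (-9.20±0.70) and C3ar1 (-6.88±0.43). The fibroblast list moved with the profibrotic genes (0 of 18 higher, 15 lower, 0 and 16 alone, adjusted p = 3.4e-25). A member was Mfap5 (-10.21±1.11). The count was 573 without macrophage control A, 761 without control B, 806 without macrophage day 14 B and 792 without monocyte control C.

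At day 28, 362 genes changed more upward in macrophages, 577 more downward and 15321 did not pass. Resident macrophage (0 of 32 higher, 25 lower, 0 and 30 alone, adjusted p = 5.8e-65) and complement genes (1 of 22 higher, 14 lower, 2 and 15 alone, adjusted p = 2.0e-34) were relatively lower in macrophages, with Dab2 (-11.02±0.72) and C1qb (-8.13±0.53). Inflammatory (1 of 30 higher, 10 lower, 2 and 13 alone, adjusted p = 2.4e-10) and profibrotic genes (2 of 29 higher, 9 lower, 2 and 13 alone, adjusted p = 7.6e-06) were relatively lower too, with Ccl2 (-5.03±0.69) and Timp1 (-5.12±0.80). Cholesterol synthesis genes were relatively higher in macrophages (7 of 23 higher, range 1 to 8, 0 lower, 9 and 0 alone, adjusted p = 7.2e-08, estimated-correlation p = 0.10). Members included Fdft1 (3.69±0.67) and Sqle (4.18±0.94). The fibroblast list was relatively lower (0 of 18 higher, 13 lower, 0 and 15 alone, adjusted p = 2.8e-24). A member was Mfap5 (-10.01±1.11). The count was 492 without macrophage control B.

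**Figure D4:**
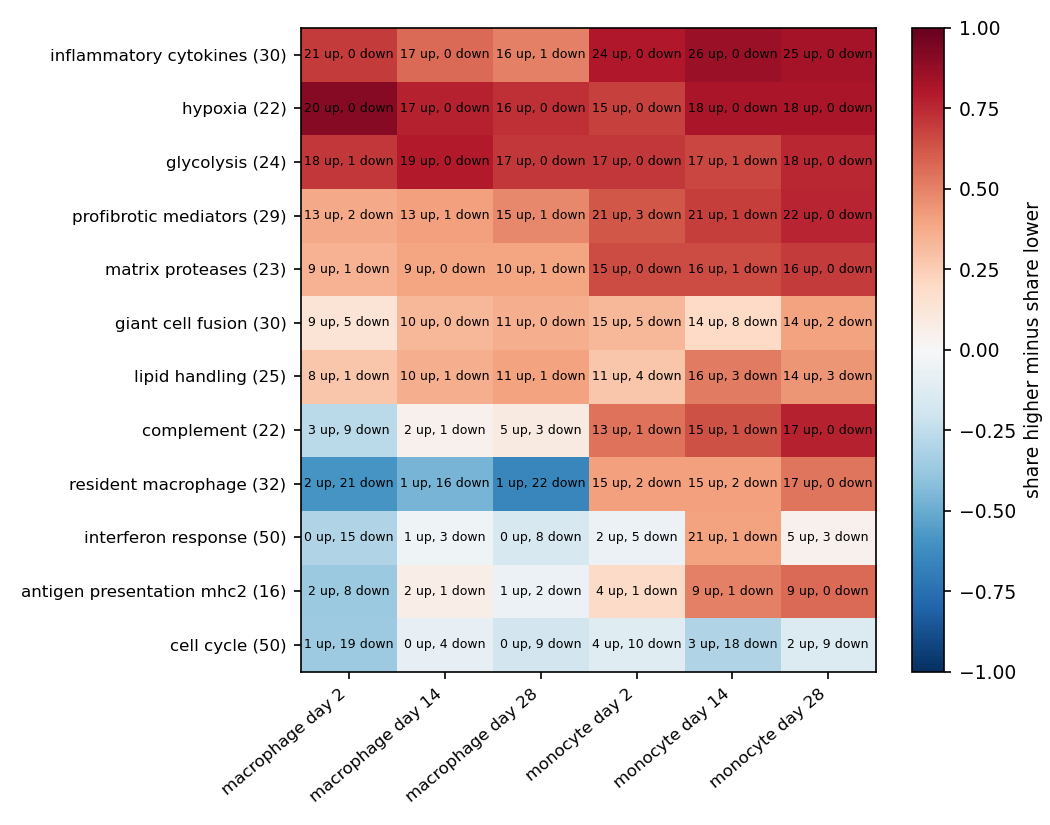
Genes higher and lower, printed as 2 numbers per cell, in 12 gene lists and the 6 comparisons with controls. The colour is the share of tested members that rose minus the share that fell.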

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

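The tests of how the neutrophil and fibroblast lists moved together were chosen only after those patterns were seen. The tests on transcript length, on depth and on other splits of the libraries were set down before their results.

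The interaction test passed 615 genes at day 2, 1227 at day 14 and 939 at day 28. The named ones, with the macrophage minus the monocyte log2 change, were C1qa -8.82, Dab2 -11.15, H2-Eb1 -2.94, Lgmn -2.93, Mrc1 -6.34, Pf4 -7.28, S100a8 9.12, S100a9 9.19, Spn 4.65, Stab1 -8.30 at day 2. The day 14 values were C3ar1 -6.88, Ccl2 -5.49, Ctsl -3.87, Cxcl2 -4.99, Dab2 -10.75, Mfap5 -10.21, Stab1 -9.20, Timp1 -6.07. Those of day 28 were C1qb -8.13, Ccl2 -5.03, Dab2 -11.02, Fdft1 3.69, Mfap5 -10.01, Sqle 4.18, Timp1 -5.12.

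Differences between time points within a cell type were tested directly. In macrophages 77 genes passed from day 2 to day 14, with log2 changes of Axl 3.82, C4b 4.46, Ccl2 -2.27, Cd74 2.30, Il6 -4.38, Itgax 3.74, Klk8 -6.44, Klk9 -9.09, Lcn2 -7.04, Olfml3 3.48, Retnlg -6.24, S100a9 -5.67, Saa3 -6.39, Slc2a3 -7.28, Slc9b2 6.71. From day 14 to day 28 the 1 gene was Zfp169 4.06. In monocytes 118 genes passed from day 2 to day 14, with Asprv1 -5.48, Chil1 -5.55, Col1a2 3.73, Cxcl10 4.22, Hmox1 1.54, Lcn2 -3.62, Mfap5 4.96, Mmp13 3.84, Mmp9 -5.21, Nr1h3 2.29, Pdgfb 3.27, Retnlg -5.02, Rilpl1 3.93, Rsad2 3.14, Sparc 4.02. From day 14 to day 28 117 passed, with Apoe 3.61, Arhgap9 3.16, Cd24a -1.85, Dubr -1.40, Ifi207 -1.30, Ifitm6 -1.69, Itgb1 1.83, Rbfa 3.07, S100a11 -1.84, Tmem70 3.67, Tsen34 3.35.

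The first pattern is the rise of oxidative phosphorylation and ribosomal protein genes beside an implant. No list result weighed here passed with an estimated correlation (p = 0.19 and 0.36 in day 2 macrophages, 0.25 for oxidative phosphorylation in day 2 monocytes and 0.51 for ribosomal genes in day 14 monocytes). The length trend differed between libraries, with slopes of 0.103 and -0.201 in macrophage controls and -0.503, -0.429 and -0.509 at day 2. Against 10000 lists matched on transcript length and level, the oxidative phosphorylation median of 1.37 lay at percentile 100 in day 2 macrophages and that of 1.29 at percentile 99.9 in day 2 monocytes. The ribosomal medians lay at percentile 100 in day 2 macrophages and 99.6 in day 14 monocytes, which argues against the length trend as the whole cause. Matched lists rose too, by 0.89 and 0.92 for oxidative phosphorylation and 0.47 and 0.51 for ribosomal genes, so a large part of each rise may belong to short transcripts in general. After thinning to equal totals 41 of 41 members stayed higher in day 2 macrophages, which argues against depth, and a change of the cells in the implant stays open. The numbers that rose there fell from 41 to 1, 25, 16 and 22 and, for ribosomal genes, from 22 to 0, 7, 3 and 6 without macrophage control A, control B, day 2 A and day 2 C. Mitochondrially encoded genes rose too, 9, 1 and 8 of 11 in macrophages at days 2, 14 and 28 and 10, 9 and 0 in monocytes. A difference in cell or RNA quality was not tested and stays open.

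The second pattern is the rise of neutrophil genes in day 2 macrophages. Cxcr2 went from 0.465 to 55.5 CPM and Ly6g from 0 to 13.3. Of the 14, 12 rose, and 7 without macrophage control A. In day 2 monocytes 5 rose and 3 fell, with Retnlg from 0.911 to 208 CPM, Cxcr2 from 1.1 to 38.5 and Ly6g from 1 to 6.21. Neutrophil cells or RNA carried through the sort may be the source, although gating on Cx3cr1 would remove cells lacking it. Members of the list moved together over the implant libraries of both cell types, with a mean correlation of 0.22 at percentile 99.9 of lists matched on level. Common regulation in the sorted cells would give this too, so it favours neither source. Of 14 members, 3 belong to another list, 6 were at 1 CPM or more in macrophage controls and 11 in monocyte controls. Transcription by the sorted cells stays open and was not tested.

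The third pattern is the rise of fibroblast genes in monocytes, 15 of 18 at day 14 (estimated-correlation p = 0.095). Mean levels at day 14 were 289 CPM for Sparc, 103 for Col1a2 and 52.6 for Mfap5. Fibroblast cells or RNA may be the source, although cells without Cx3cr1 and Ly6C would not pass the gate. List members moved together over the same libraries, with a mean correlation of 0.46 at percentile 100 of matched lists, which common regulation in monocytes would give too. Of the 18, 1 belongs to another list, and 1 was at 1 CPM or more in monocyte controls against 15 in macrophage controls. Outside the fibroblast list 20 of 28 profibrotic genes rose in day 14 monocytes and 1 fell, and expression by the monocytes stays open.

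Other splits of the libraries were refitted. Where 3 libraries stood against 3, the 10 splits are too few for a share under 0.05. The real count and the highest other were 4389 and 1 in monocytes at day 2 against controls, 6132 and 0 at day 14, and 2965 and 1 at day 28. From day 2 to day 14 they were 77 and 0 in macrophages and 118 and 96 in monocytes, and from day 14 to day 28 they were 117 and 2 in monocytes. Between the cell types they were 556 and 0 at day 2, 1523 and 0 at day 14, and 409 and 0 at day 28. In each of these 9 cases 1 of the 10 splits, the real one, gave as many genes. For macrophages from day 14 to day 28 the real count was 1, and 3 of the 10 splits gave as many. The highest, 211, set day 14 A with day 28 A and B against day 14 B and C with day 28 C, and what sets these libraries apart was not tested. Over the 4 monocyte times 1 of 100 splits gave 4878 genes, the next giving 3879, 3083 and 3061. Between the cell types over the implant days 1 of 100 gave 2103, the next 217. Chance is unlikely for both, but not excluded.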

How the results depend on the processing

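The alternatives with a covariate for the transcript length trend, without 3 libraries together, and with matched lists were chosen only after the results were seen. Counts are limited by the small groups, and the lowest levels by depth, since a gene with 3 counts lies at 0.091 to 0.32 CPM before TMM scaling. The slope of the transcript length trend was lower than in controls in each library at days 2 and 14, so it cannot be fully parted from the implant there, while at day 28 it overlapped with controls. Counts of genes below are numbers that passed, and those given lay more than 1.5 times above or below the reported count. A count does not say which genes passed. Where a construction does not show the cause (fewer libraries, more genes tested), the cause was not tested.

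No named gene or list changed direction under the alternatives that were run. With DESeq2 size factors 19 of 19 counts stayed within 1.5 times, and with all libraries in the overall tests 2 of 2 did. DESeq2 moved 11 of 19. Against controls DESeq2 gave 2238 in macrophages at day 14. Between days DESeq2 gave 334 in macrophages from day 2 to 14, 40 from day 14 to 28, 586 in monocytes from day 2 to 14 and 1513 from day 14 to 28. Between cell types DESeq2 gave 1176 at day 2, 2896 at day 14 and 1199 at day 28. For the interaction DESeq2 gave 1077 at day 2, 2213 at day 14 and 1471 at day 28. With limma voom 15 of 19 moved. Against controls voom gave 4696 in macrophages at day 2, 2455 at day 14, 3134 at day 28 and 7340 in monocytes at day 2. Between days voom gave 721 in macrophages from day 2 to 14, 79 from day 14 to 28, 538 in monocytes from day 2 to 14 and 334 from day 14 to 28. Between cell types voom gave 3541 in controls, 1647 at day 2, 2869 at day 14 and 1167 at day 28. For the interaction voom gave 1482 at day 2, 2685 at day 14 and 1636 at day 28. With no low count filter 10 of 19 moved. Between days the unfiltered fit gave 682 in macrophages from day 2 to 14, 252 from day 14 to 28, 741 in monocytes from day 2 to 14 and 1523 from day 14 to 28. Between cell types the unfiltered fit gave 1033 at day 2, 2494 at day 14 and 1285 at day 28. For the interaction the unfiltered fit gave 1240 at day 2, 2366 at day 14 and 1602 at day 28. With only the groups compared 7 of 17 moved. Against controls these smaller fits gave 693 in macrophages at day 28. Between days these smaller fits gave 145 in macrophages from day 2 to 14, 0 from day 14 to 28, 72 in monocytes from day 2 to 14 and 230 from day 14 to 28. Between cell types these smaller fits gave 1 at day 28. For the interaction these smaller fits gave 575 at day 28.

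Thinning to the lowest total moved 2 of 19. Between days thinned counts gave 0 in macrophages from day 14 to 28 and 259 in monocytes from day 14 to 28. The length covariate moved 7 of 19. Against controls the covariate gave 1336 in macrophages at day 2, 2573 in monocytes at day 2 and 3108 at day 14. Between days the covariate gave 0 in macrophages from day 14 to 28, 198 in monocytes from day 2 to 14 and 491 from day 14 to 28. Over 4 monocyte times the covariate gave 1612. Without macrophage day 2 B, macrophage day 14 C and monocyte control B, which differed in length trend or mitochondrial share, 5 of 19 moved. Between days the other libraries gave 41 in macrophages from day 2 to 14, 2 from day 14 to 28 and 227 in monocytes from day 14 to 28. Between cell types the other libraries gave 327 at day 2 and 1391 over implant days.

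A replicate block moved 7 of 19 counts. Between days it gave 0 in macrophages from day 14 to 28 and 2 in monocytes from day 14 to 28. Between cell types it gave 1191 in controls and 250 at day 28. For the interaction it gave 370 at day 2, 568 at day 14 and 520 at day 28. Whether the replicate letters pair libraries is open. After group means were removed, 4 of 11 same-letter pairs correlated above 0.1 (range -0.26 to 0.47, controls 0.35 and 0.47), against -0.47 to 0.34 for other letters.

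Leaving out 1 library moved 57 of 143 counts. Against controls the lowest and highest were 826 to 2287 in macrophages at day 2, 417 to 1128 at day 14, 689 to 1880 at day 28, 2724 to 4345 in monocytes at day 2, 4635 to 5811 at day 14, 1932 to 2909 at day 28. Between days they were 29 to 108 in macrophages from day 2 to 14, 0 to 24 from day 14 to 28, 0 to 159 in monocytes from day 2 to 14, 0 to 252 from day 14 to 28. Between the cell types they were 1111 to 1754 in controls, 269 to 384 at day 2, 635 to 1432 at day 14, 69 to 1323 at day 28 and 1756 to 2208 over implant days. Interactions had 380 to 561 at day 2, 573 to 1297 at day 14, 492 to 1060 at day 28, and the 4 monocyte times 3123 to 5224. A group left with 1 library was assumed to vary like the others.

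Among the named genes, 21 of 290 calls ended with only the groups compared, 18 with the block, 14 without the 3 libraries, 9 with the length covariate, 2 with limma voom and 1 after thinning. None ended with DESeq2 size factors, with no filter or, among 287, with DESeq2. Leaving out 1 library at a time ended 168 of 1882. At least 1 library did so for 15 of 15 genes named for monocytes from day 2 to 14, 11 of 11 from day 14 to 28, 7 of 15 for macrophages from day 2 to 14, and 1 of 33 for monocytes at day 2 against controls. Other alternatives ended at least 1 call for 7 of 15, 11 of 11 and 7 of 15 of these, and for 12 of 12 between the cell types at day 28. Of the lists, 35 of 124 no longer passed with an estimated correlation and 5 with fry. Leaving out 1 library moved the number of members called in the list's direction more than 1.5 times in 47 of 124 lists, and to 0 in 9. Against matched lists 7 no longer passed and 1 passed that had not.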

Other observations

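Which values to describe in this part was decided after the results were seen, and no explanation of them was tested. The gene tests and lists were set beforehand, while counts of list members at 1 CPM were added later. Transcripts of genes behind the sort were followed within each cell type. The fractalkine receptor gene Cx3cr1 was at 501 CPM in control monocytes and at 81.1, 80.4 and 124 CPM at days 2, 14 and 28 (log2 fold changes and CPM: -2.63±0.38, 81.1 against 501 CPM at day 2). In macrophages it fell at day 2 (-1.77±0.40, 28.4 against 96.9 CPM). The leukocyte gene Ptprc fell in monocytes at day 2 (-0.80±0.27, 936 against 1627 CPM) and the lysosomal marker Cd68 rose at day 14 (1.89±0.29, 3311 against 891 CPM). The growth factor receptor gene Csf1r fell in macrophages at day 2 (-1.74±0.43, 708 against 2367 CPM). The 3 monocyte controls held granule gene transcripts at different levels, with Ngp at 1152, 1394 and 779.8 CPM, Camp at 324, 413 and 219.7 CPM and Elane at 43.9, 55.6 and 29.8 CPM in replicates A, B and C.

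Lists of microbial sensing and migration moved in both cell types. Pattern recognition genes (13 of 41 higher, 4 lower, 14 and 5 alone, adjusted p = 1.6e-05, estimated-correlation p = 0.13, percentile 88.2) and chemokine receptor and adhesion genes (11 of 29 higher, range 6 to 10, 2 lower, 16 and 4 alone, adjusted p = 2.0e-04, estimated-correlation p = 0.060) were higher in macrophages at day 2. The lipopolysaccharide co-receptor Cd14 (4.11±0.31, 7629 against 442 CPM) and the formyl peptide receptor Fpr1 (3.83±0.69, 216 against 15.2 CPM) rose. In monocytes at day 14 the pattern recognition list was higher (18 of 41 higher, 9 lower, 18 and 11 alone, adjusted p = 3.3e-04, estimated-correlation p = 0.20, percentile 83.5), with Cd14 (6.21±0.29, 13461 against 182 CPM), and so was the chemokine receptor list at day 2 (13 of 29 higher, 4 lower, adjusted p = 2.7e-04, estimated-correlation p = 0.088). Unfolded protein response genes were higher in monocytes at day 2 (11 of 24 higher, 2 lower, 12 and 2 alone, adjusted p = 0.0064, estimated-correlation p = 0.20), with the chaperone Calr (1.55±0.21, 707 against 241 CPM).

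In lists of other cell types, ranges in parentheses are those with 1 library left out. Of 14 T cell genes, 13 were at 1 CPM or more in day 2 macrophage library C, 7 in A, 7 in B and 3 in each control. In day 2 macrophages 1 rose (0 to 2), and in day 2 monocytes 8 rose (3 to 8). Of 17 dendritic cell genes, 7 fell (6 to 8) and 1 rose (1 to 1) in day 14 monocytes. Of 10 B cell genes, 3 fell (1 to 3) and 1 rose (0 to 1) in day 2 macrophages, and 3 fell (3 to 5) and 2 rose (1 to 2) in day 14 monocytes. Of 9 muscle genes, 3 fell (1 to 2) in day 2 macrophages, and 4 rose (0 to 4) in day 28 monocytes. Of 13 endothelial genes, 3 rose (2 to 4) in day 28 monocytes, where 0 fell (0 to 1). Among 5 erythroid genes 0 passed by the edgeR quasi-likelihood test in any of the 6 comparisons with controls, and up to 2 rose in day 2 monocytes with 1 library left out. In day 14 monocytes 2 of 9 natural killer genes rose (0 to 2), as did 3 of 8 adipocyte genes (1 to 2), 2 of 4 keratinocyte genes (2 to 2) and 1 of 8 mast cell, eosinophil and basophil genes (1 to 1), while 1 adipocyte gene fell (0 to 1).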
